A study of Homo sapiens with 4 samples.

How the data were processed

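The series held 4 Affymetrix microarrays of MCF7 cells, 2 of untreated cells and 2 of cells treated with PHA-848125. Per the labels' protocols, cells were grown in medium with 10% serum for 24 h before treatment, exposed for 6 h to 5 times the IC50, and lysed. A one-cycle kit was used to make biotin-labelled cRNA, with 1.5 µg of total RNA as the input for each array. The labels do not say whether the untreated cells received vehicle, nor whether replicates came from separate cultures, so that p-values measure the spread between these samples, which may be technical.

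The deposited intensity values were linear signals, 1 per probe set and array, and the submitters' processing notes name MAS5 without a version. In the values, the mean signal after trimming 2% at each end was 500 on every array, so each array had been scaled to that target. The table used here held no detection calls. It had 54675 probe sets, of which 62 were controls. Probe sets were paired with genes through the platform annotation: 41091 had 1 gene symbol, 1801 had several and 11721 had none, and only those with 1 symbol were named. Of these, 41037 took their current symbol from the Entrez identifier in a RefSeq table of assembly GRCh38.p14, and 54 kept the annotation's symbol. That table also gave gene length, gene type and which genes are neighbours.

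The values were kept at the deposited scaling and taken as log2(signal + 16). For each gene the probe set with the highest mean over the 4 arrays was used, which gave 19775 genes, and a gene was tested where that mean lay above the median of all 54613 non-control probe sets (log2 6.18). This left 12267 genes. Probe sets of a gene often disagreed: of 6025 genes with several probe sets above the threshold, 592 had probe sets called in both directions. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend; 2 residual and 6.42 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 4 arrays, the number of arrays limits the precision of every value.

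Before the data were examined, 35 gene lists were written, of which 34 had the 5 tested members required. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation and fry. The genes named were fixed by a rule written at the same time: the 10 largest rises and 10 largest falls among called genes whose groups did not overlap, the 3 called members with the largest change in each list (or the 2 with the smallest p where fewer than 3 were called), and a fixed set of CDK, cyclin and related genes. The rule named 127 genes, of which 125 were tested. Of the called ones, 8 (EGFR, ERN1, LUC7L3, MDM2, MYB, PER2, PSMC2 and ZFAS1) had another probe set called in the opposite direction.

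The method was tested on simulated data in which 200 genes were changed between 2 arrays and 2 arrays. Among those that passed the level filter, recovery was 64.6% of 65 genes at a log2 change of 0.5, 93.8% of 65 at 1 and 100% of 60 at 2, and 10 of 12081 unchanged genes were called. None of 20 simulated lists without a change was called. Noise was drawn independently for each probe set, and the 200 changes were split evenly between rises and falls. The simulation therefore cannot show how often correlated lists, or a shift of most genes, give false calls. The spread of the noise was set by the level alone, whereas real genes of equal level can differ in spread. Recovery and false calls may therefore look too favourable.

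The alternatives tried were pseudocounts of 1 and 64, no level filter and a filter at the 75th percentile, 5 other scalings (median, quantile, cyclic loess, hybridisation spikes and poly-A spikes), other choices of probe set, other variance priors, the replicate number as a block, other thresholds, and leaving out each array in turn. Scaling to the poly-A spikes was added after seeing the data. Quality was described by the control probe sets. The 3' to 5' signal ratio of GAPDH was 0.978 and 0.967 on the untreated arrays and 0.958 and 0.932 on the treated arrays, and that of actin was 1.21, 1.13, 1.24 and 1.22. The brightest 2% of probe sets held 41.1% and 41.4% of the signal on the untreated arrays and 49.6% and 50.9% on the treated arrays. The genes TP53 and NTRK1 were not analysed here.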

Results

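Gene expression was measured in MCF7 cells, an oestrogen receptor-positive human mammary adenocarcinoma line, with and without PHA-848125, an inhibitor of cyclin-dependent kinases (CDKs) and of the TRK receptor tyrosine kinases. There were 4 microarrays, 2 of untreated cells and 2 of cells exposed for 6 h to a dose of 5 times the IC50. The deposited values were linear signals with the same trimmed mean of 500 on every array. The median signal was 56.5 and 57.0 on the untreated arrays and 67.0 and 63.4 on the treated arrays. Across the 12267 genes tested, the log2 values of replicate arrays correlated at 0.991 in the untreated group and 0.987 in the treated group. Between groups they correlated at 0.904 to 0.907. Changes below are log2 differences, treated minus untreated, on the log2(signal + 16) scale, with the standard error of the limma fit and n = 2 arrays per group. This scale understates the change of genes with low signals.

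The comparison asked which transcripts differed in MCF7 cells after 6 h with PHA-848125. The cell cycle genes CCNE2, NDC80 and AURKA changed by -4.56, -4.52 and -4.00, and were lower under every scaling tried. The histone gene H4C4 changed by 4.28, the p53 target gene GADD45A by 3.26 and the immediate early gene EGR1 by 2.27, and these were higher under every scaling tried. Of 12267 genes tested, 7646 changed at an adjusted p under 0.05, 3597 of them higher and 4049 lower. At least 2-fold changes were found for 2526 genes, of which 611 were higher and 1915 lower.

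The split between higher and lower calls depended on how the arrays were scaled. The deposited scaling gave a median change of all tested genes of 0.01, and 47.0% of the calls were higher. Scaling to the array median moved the median change to -0.18, with 2537 genes higher and 4932 lower (34.0% higher). The bacterial spike-in controls were brighter on the treated arrays, by 0.50 ± 0.07 (SD over 18 probe sets) for the hybridisation spikes and by 0.81 ± 0.09 (SD over 24 probe sets) for the poly-A spikes. Scaled to the hybridisation spikes, the median change was -0.46, with 1085 genes higher and 6368 lower (14.6% higher). Scaled to the poly-A spikes, it was -0.76, with 271 higher and 7798 lower (3.36% higher). The directions given below hold for the deposited scaling. Against the poly-A spikes the median of each of the 34 gene lists tested lay below 0, with the exception of the histone list. Against the hybridisation spikes the medians above 0 were those of the histone, fibroblast, respiratory chain, ribosomal protein, snoRNA host, common reference and leukocyte lists.

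**Figure D1:**
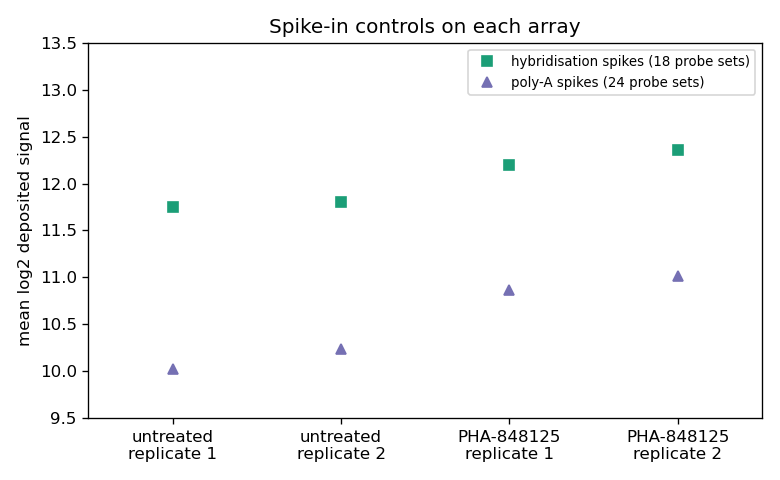
Mean log2 deposited signal of the hybridisation spike probe sets (squares, 18 probe sets) and the poly-A spike probe sets (triangles, 24 probe sets) on each of the 4 arrays, named on the x axis by group and replicate. Both kinds of spike were higher on both PHA-848125 arrays than on either untreated array, on average by 0.50 and 0.81.

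Of 34 lists of genes fixed before the data were examined and large enough to test, 8 were shifted against all other genes by limma's camera test with a preset correlation of 0.01, 3 lower and 5 higher. None was called when the correlation between genes was estimated from the arrays. The lowest adjusted p was then 0.289, and 3 lists had an unadjusted p under 0.05. With 2 residual degrees of freedom that estimate is unstable. The test then also rests on those 2 degrees of freedom, which by itself raises its p-values. These p-values therefore cannot show that correlation between genes explains the loss. For the G2/M, G1/S and p53 lists the estimated correlations were -0.0059, -0.012 and -0.012. These lie below the preset, which argues against correlation as the reason in these lists. The other called lists had estimates above the preset. The rotation test fry, which tests each list by itself and not against other genes, called 30, all but the ATF4, NRF2, proteasome and interferon lists. Adjusted over the list alone, the counts of changed members given below were identical unless another count is given.

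The G2/M and mitotic genes were lower as a group. Of 58 members tested, 53 fell, 2 rose and 3 were not called, and 54 were lower when adjusted over the list alone. The median change was -1.68 (camera adjusted p = 1.4e-16, and adjusted p = 0.29 with an estimated correlation), and it stayed negative under every scaling tried, between -1.59 and -2.46. NDC80, a component of the outer kinetochore, fell from a signal of 2545 ± 140 to 95.8 ± 8.31 (SD, n = 2), a log2 change of -4.52 ± 0.13 (SE; limma adjusted p = 1.0e-07). AURKA, which encodes Aurora kinase A, changed by -4.00 ± 0.08 (limma adjusted p = 6.8e-08). TTK, the spindle checkpoint kinase, changed by -3.45 ± 0.10. The members that rose were CDC20 (1.02) and BIRC5 (0.62), which were named after their values were seen.

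Genes of DNA replication and the G1/S transition were also lower as a group, with 33 of 52 members lower, 8 higher (9 adjusted over the list alone) and 11 not called. Their median change was -0.72 (camera adjusted p = 9.9e-05, and adjusted p = 0.41 with an estimated correlation). The largest falls were those of CCNE2 (cyclin E2, -4.56 ± 0.10), POLD3 (a subunit of DNA polymerase delta, -3.69 ± 0.20) and CDC6 (a replication licensing factor, -3.15 ± 0.20). Another probe set of POLD3 above the level threshold was not called. Of 30 homologous recombination and Fanconi anaemia genes, 23 fell, 1 rose and 6 were not called, with a median of -0.70 (camera adjusted p = 3.9e-05, and adjusted p = 0.41 with an estimated correlation). EXO1, a 5' to 3' exonuclease, changed by -2.49, FANCL, the E3 ligase of the Fanconi core complex, by -2.26, and TOPBP1, an activator of the ATR checkpoint kinase, by -1.88. Both lists kept a negative median under every scaling tried.

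**Figure D2:**
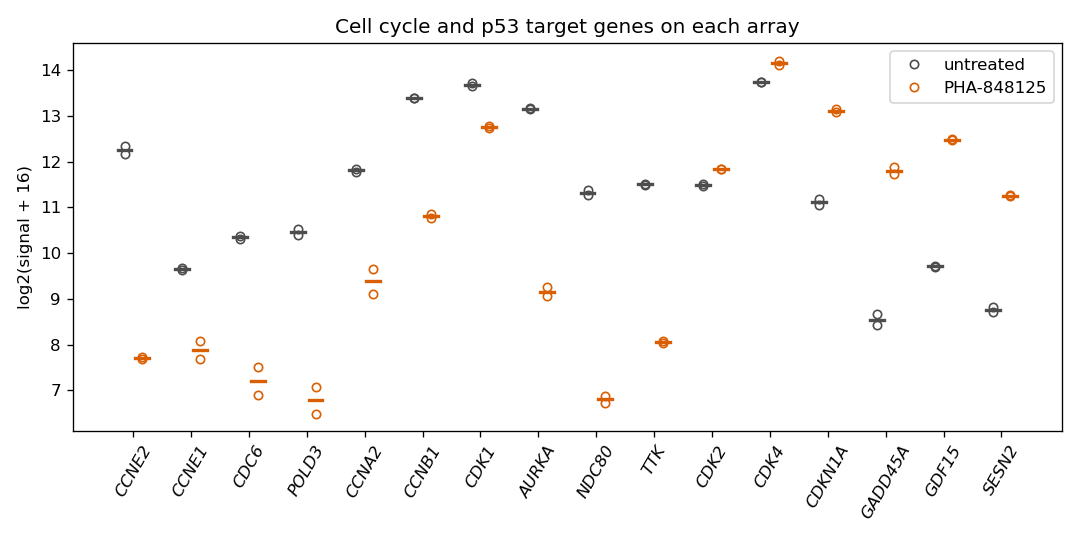
Log2(signal + 16) of 16 cell cycle and p53 target genes on each array, untreated in grey and PHA-848125 in orange, with open circles for the 2 arrays of a group and bars for their mean. CCNE2 and NDC80 were lower on both treated arrays by more than 4 log2 units, whereas CDKN1A and GADD45A were higher on both.

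The cyclins, CDKs and CDK inhibitors were not called against other genes by camera. The fry test, which called 30 of the 34 lists, called this list lower (adjusted p = 0.0071). Of 31 tested, 15 fell, 9 rose (10 adjusted over the list alone) and 7 were not called, with a median of -0.09 (camera adjusted p = 0.47). The cyclins of the S and M phases fell, with changes of -2.42 ± 0.15 for CCNA2 and -2.58 ± 0.06 for CCNB1, and CCNE1 changed by -1.77 ± 0.16. Among the kinases, CDK1 changed by -0.93 ± 0.05 and CDK7, the CDK-activating kinase, by -0.98 ± 0.09. CDK2 (0.34 ± 0.06), CDK4 (0.42 ± 0.05) and CDK9 (0.37 ± 0.12), the catalytic subunit of P-TEFb, were higher at the deposited scaling, but their sign turned under spike scaling, to -0.47, -0.38 and -0.43 against the poly-A spikes, and CDK4 also turned with quantile normalization (-0.084). The call for CDK9 was also lost without untreated replicate 1 or without PHA-848125 replicate 2. CDK5 was not called at the deposited scaling (-0.02 ± 0.12, limma adjusted p = 0.92), but changed by -0.51 against the hybridisation spikes and -0.82 against the poly-A spikes. RB1, which encodes the retinoblastoma protein phosphorylated by CDKs, changed by -0.34 ± 0.09 (limma adjusted p = 0.010), a call lost without untreated replicate 2.

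For CCND1, which encodes cyclin D1, the probe sets disagreed. The probe set chosen by the fixed rule changed by 0.04 ± 0.08 and was not called, whereas the other, which was brighter in untreated cells, changed by -1.91 ± 0.08. MCL1, an anti-apoptotic BCL2 family gene, was not called at its chosen probe set at the deposited scaling (-0.02 ± 0.07). That probe set changed by -0.28 with quantile normalization and with loess, and by -0.52 and -0.83 against the hybridisation and poly-A spikes. Of the 5 other MCL1 probe sets above the level threshold, 3 were called lower, with changes of -0.55 to -0.66. TP53 and NTRK1 were not analysed here. The only TRK receptor gene tested was NTRK3, which was not called (0.32 ± 0.33).

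The replication-dependent histone genes rose as a group. Of 34 tested, 30 rose (31 adjusted over the list alone), none fell and 4 were not called. The median change was 1.77 (camera adjusted p = 1.3e-11, and adjusted p = 0.41 with an estimated correlation), and it stayed positive under every scaling tried, at 1.29 against the hybridisation spikes and 1.00 against the poly-A spikes. H4C4, a histone H4 gene, rose from a signal of 116 ± 1.45 to 2551 ± 137 (SD, n = 2), a log2 change of 4.28 ± 0.12. H1-4, a linker histone gene, changed by 3.70 ± 0.25 and H3C2, a histone H3 gene, by 3.39 ± 0.15. Histone genes are near-identical copies, so the signal of a single gene is uncertain.

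The p53 target genes were higher as a list, with 17 of 35 members higher, 4 lower and 14 not called. Their median change was 0.33 at the deposited scaling and turned to -0.16 and -0.47 against the hybridisation and poly-A spikes (camera adjusted p = 0.0014 at the deposited scaling, and adjusted p = 0.41 with an estimated correlation). GADD45A, a stress-induced growth arrest gene, changed by 3.26 ± 0.11, GDF15, a secreted stress cytokine, by 2.77 ± 0.07, and SESN2, a stress-induced regulator of mTORC1, by 2.50 ± 0.09. CDKN1A, which encodes the CDK inhibitor p21, rose from a signal of 2213 ± 128 to 8847 ± 279 (SD, n = 2), a log2 change of 1.99 ± 0.07. These 4 genes were also higher against the poly-A spikes, CDKN1A by 1.19. MDM2, the E3 ligase that targets p53, was lower at its chosen probe set (-0.74 ± 0.10). Of its 7 other probe sets above the level threshold, 1 was also called lower (-0.70) and 3 were called higher, the largest of these rises being 2.76.

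Genes of transcription elongation and of the early transcriptional response went both ways. Of 25 P-TEFb and elongation factor genes, 14 fell, 7 rose and 4 were not called (median -0.56, camera adjusted p = 0.093). The list was called lower without a level filter and against the poly-A spikes. MEPCE, which encodes the capping enzyme of 7SK RNA, changed by -3.05 ± 0.13, LEO1, a subunit of the PAF1 complex, by -2.42 ± 0.09, and the elongation factor gene ELL3 by -2.19 ± 0.17. Of 34 immediate early genes, 17 rose, 12 fell and 5 were not called (median 0.36, camera adjusted p = 0.47). The largest changes in that list were those of the transcription factor genes NR4A1 (2.47 ± 0.48), EGR1 (2.27 ± 0.10) and FOS (1.79 ± 0.13), all 3 also higher against the poly-A spikes. The MAPK feedback list, which shares EGR1, had 8 genes lower, 4 higher and 6 not called (median -0.36, camera adjusted p = 0.50), with SPRED1 at -2.94 and EPHA4 at -2.72.

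MYC changed by -1.56 ± 0.10 (limma adjusted p = 3.1e-06). Of 39 MYC target and ribosome biogenesis genes, 17 fell (18 adjusted over the list alone), 11 rose and 11 were not called (median -0.13, camera adjusted p = 0.60). Its largest changes were those of PPRC1 (-2.11), WDR12 (-1.80) and BYSL (-1.72). Among 37 splicing factor and CLK genes, 16 rose, 12 fell and 9 were not called (camera adjusted p = 0.61). SRSF7 changed by -2.72 ± 0.06 and SRSF5 by -1.66 ± 0.11, both SR splicing factors, and LUC7L3 by -1.66 ± 0.14. Other probe sets of LUC7L3 were called in each direction.

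Neither list of apoptosis genes was called by camera. The fry test, which called 30 of the 34 lists, called both lower (adjusted p = 0.0027 for the pro-apoptotic and 0.026 for the anti-apoptotic list). Of 19 pro-apoptotic BCL2 family and caspase genes, 8 fell, 6 rose and 5 were not called (median -0.32, camera adjusted p = 0.61), with BIK at -2.29, CASP8 at -1.92 and BOK at -1.04. Of 11 anti-apoptotic genes, 5 fell, 3 rose and 3 were not called (median -0.24, camera adjusted p = 0.77). BCL2L2 changed by -1.56, BAG1 by 1.10 and TNFAIP3 by 0.90.

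Genes of the ribosome and of the respiratory chain were higher at the deposited scaling. Of 51 ribosomal protein genes, 50 rose and 1 was not called, with a median of 0.60 that turned to -0.028 with loess normalization and -0.21 against the poly-A spikes (camera adjusted p = 1.4e-16 at the deposited scaling, and adjusted p = 0.61 with an estimated correlation). With quantile normalization their median was 0.0337, beside 0.0345 for all genes, and the call was lost with both normalizations. RPL36 changed by 0.91, RPS9 by 0.80 and RPS12 by 0.74 at the deposited scaling, and RPS9 and RPS12 turned negative against the poly-A spikes. Of 68 nuclear-encoded respiratory chain genes, 59 rose, 1 fell and 8 were not called, with a median of 0.63 that turned to -0.17 against the poly-A spikes (camera adjusted p = 3.3e-16 at the deposited scaling, and adjusted p = 0.54 with an estimated correlation). UQCR11, a complex III subunit gene, changed by 1.15, and the complex I subunit genes NDUFA1 and NDUFB11 by 1.08 and 0.99.

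Common reference genes were not stable in this comparison. Of 15 tested, 10 rose, 3 fell and 2 were not called, with a median of 0.54 that turned to -0.029 with quantile normalization, -0.083 with loess and -0.27 against the poly-A spikes (camera adjusted p = 0.015 at the deposited scaling, and adjusted p = 0.54 with an estimated correlation). The call was lost under each of the 5 other scalings and with only plain-suffix probe sets. TBP, the TATA-binding protein gene, changed by -2.70 ± 0.20 and was lower under every scaling tried. B2M changed by 0.85 and GUSB by 0.74 at the deposited scaling, but by 0.042 and -0.062 against the poly-A spikes. Proteasome genes went both ways, 15 higher, 8 lower and 8 not called of 31 (median 0.13 at the deposited scaling, -0.068 with median scaling, -0.13 with quantile normalization and -0.14 with loess, camera adjusted p = 0.26). The list was called lower with quantile normalization and higher with only plain-suffix probe sets. PSMC6 changed by -1.46, PSMC2 by -1.01 and PSMB3 by 0.76, and PSMC2 had another probe set called higher. Of 8 snoRNA host genes, 5 rose, 1 fell and 2 were not called (median 0.57, camera adjusted p = 0.082), with SNHG17 at 2.10, ZFAS1 at 0.82 and SNHG32 at 0.81. ZFAS1 had another probe set called lower, and the list was called higher against the hybridisation spikes, over all probe sets and without PHA-848125 replicate 1.

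ESR1, which encodes the oestrogen receptor alpha of these cells, changed by -0.37 ± 0.05 (limma adjusted p = 0.00027). Oestrogen receptor target genes were split, 15 higher, 13 lower and 5 not called of 33 (camera adjusted p = 0.86), and the largest changes were falls of MYB (-2.93), STC2 (-2.48) and MYC. MYB had another probe set called higher. Of 18 luminal breast epithelial markers, 11 rose, 4 fell and 3 were not called (median 0.33 at the deposited scaling, -0.069 with quantile normalization and -0.14 with loess, camera adjusted p = 0.062). ELF3 changed by -1.07, TFF3 by 1.03 and XBP1 by -0.77. The list was called higher without a level filter, with the mean of all probe sets, with the replicate number as a block and without PHA-848125 replicate 1. Of 10 basal epithelial and mesenchymal markers tested, 4 rose, 1 fell and 5 were not called (median 0.17 at the deposited scaling and -0.016 with median scaling, camera adjusted p = 0.47), with ACTA2 at 1.43, EGFR at 1.07 and FN1 at 0.83. The EGFR call was lost without untreated replicate 2 or PHA-848125 replicate 2, and another EGFR probe set was lower. Of 6 fibroblast markers, 3 rose and 3 were not called (median 0.67, camera adjusted p = 0.12), TAGLN by 1.18, COL5A1 by 0.82 and COL1A1 by 0.70. Of 7 leukocyte markers, FCER1G (1.06) and LCP1 (0.75) rose and 5 were not called (median 0.47, camera adjusted p = 0.47). Both calls were lost without untreated replicate 1, and that of FCER1G also without untreated replicate 2 or PHA-848125 replicate 2.

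Stress and signalling lists were mixed. Of 14 circadian clock genes, 10 fell, 1 rose and 3 were not called (median -0.59, camera adjusted p = 0.081), with CRY1 at -1.81, PER2 at -1.51 and PER3 at -1.36. PER2 had another probe set called higher, and the list was called lower without a level filter and over all probe sets. Of 19 heat shock genes, 10 fell (11 adjusted over the list alone), 6 rose and 3 were not called (median -0.38, camera adjusted p = 0.38), a list called lower with quantile and loess normalization. The co-chaperone genes CHORDC1, HSPH1 and STIP1 changed by -2.01, -1.49 and -1.19. Of 21 unfolded protein response genes, 13 rose, 6 fell and 2 were not called (median 0.38, camera adjusted p = 0.11), with ERN1 at 1.41, SEC24D at -1.08 and CALR at 0.84. ERN1 had another probe set called lower. Of 29 ATF4 and amino acid response genes, 13 fell, 9 rose and 7 were not called (median -0.10, camera adjusted p = 0.69). SESN2 was the largest rise among its 3 largest changes, beside STC2 and DDIT3 (-1.74), whose call was lost without untreated replicate 1. Of 22 NRF2 target genes, 8 fell, 7 rose and 7 were not called (camera adjusted p = 0.63), with OSGIN1 at -1.73, GCLM at -1.52 and FTL at 0.90. The OSGIN1 call was lost without untreated replicate 1. Of 32 hypoxia and glycolysis genes, 18 rose, 10 fell and 4 were not called (median 0.30 at the deposited scaling and -0.0032 with quantile normalization, camera adjusted p = 0.17). Its largest changes were those of PFKFB3 (-1.65), KDM3A (-1.48) and EGLN3 (-1.40).

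Of 28 interferon-stimulated genes, 11 rose, 8 fell and 9 were not called (camera adjusted p = 0.47), with PARP9 at -2.42, OAS1 at -2.26 and USP18 at -1.28. With a pseudocount of 1 the highest mean fell on another probe set of PARP9, so the log2 change of PARP9 was -0.21 and was not called. The treated signal of the probe set used here was 51.9 ± 57.0 (SD, n = 2). Of 15 NF-kB target genes, 6 rose, 2 fell and 7 were not called (median 0.16 at the deposited scaling and -0.038 with median scaling, camera adjusted p = 0.32), NFKBIE by -1.18, REL by 1.01 and TNFAIP3 by 0.90. Of 17 TGF-beta and BMP response genes, 7 fell, 6 rose and 4 were not called (median -0.17, camera adjusted p = 0.63), with SKIL at -1.95, SKI at -1.85 and BMP4 at -1.78. The BMP4 call was lost without untreated replicate 1. Of 19 cholesterol synthesis genes, 8 fell, 7 rose and 4 were not called (camera adjusted p = 0.86), with STARD4 at -2.83, HSD17B7 at -1.19 and IDI1 at -1.15. Read by plain-suffix probe sets alone, the log2 change of IDI1 was 0.39. Of 368 ZNF zinc finger genes, 137 fell (135 adjusted over the list alone), 75 rose and 156 were not called (median -0.23, camera adjusted p = 0.32). ZNF165 changed by -3.88, ZNF680 by -3.70 and ZNF770 by -3.44. Median, mean and test direction differed in sign in 5 lists. The median and mean were -0.03 and -0.23 with an upward test for oestrogen receptor targets, 0.0018 and -0.23 with a downward test for cholesterol synthesis, and 0.06 and -0.12 for NRF2 targets, 0.12 and -0.06 for splicing factors and 0.17 and -0.06 for interferon-stimulated genes, these last with an upward test.

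**Figure D3:**
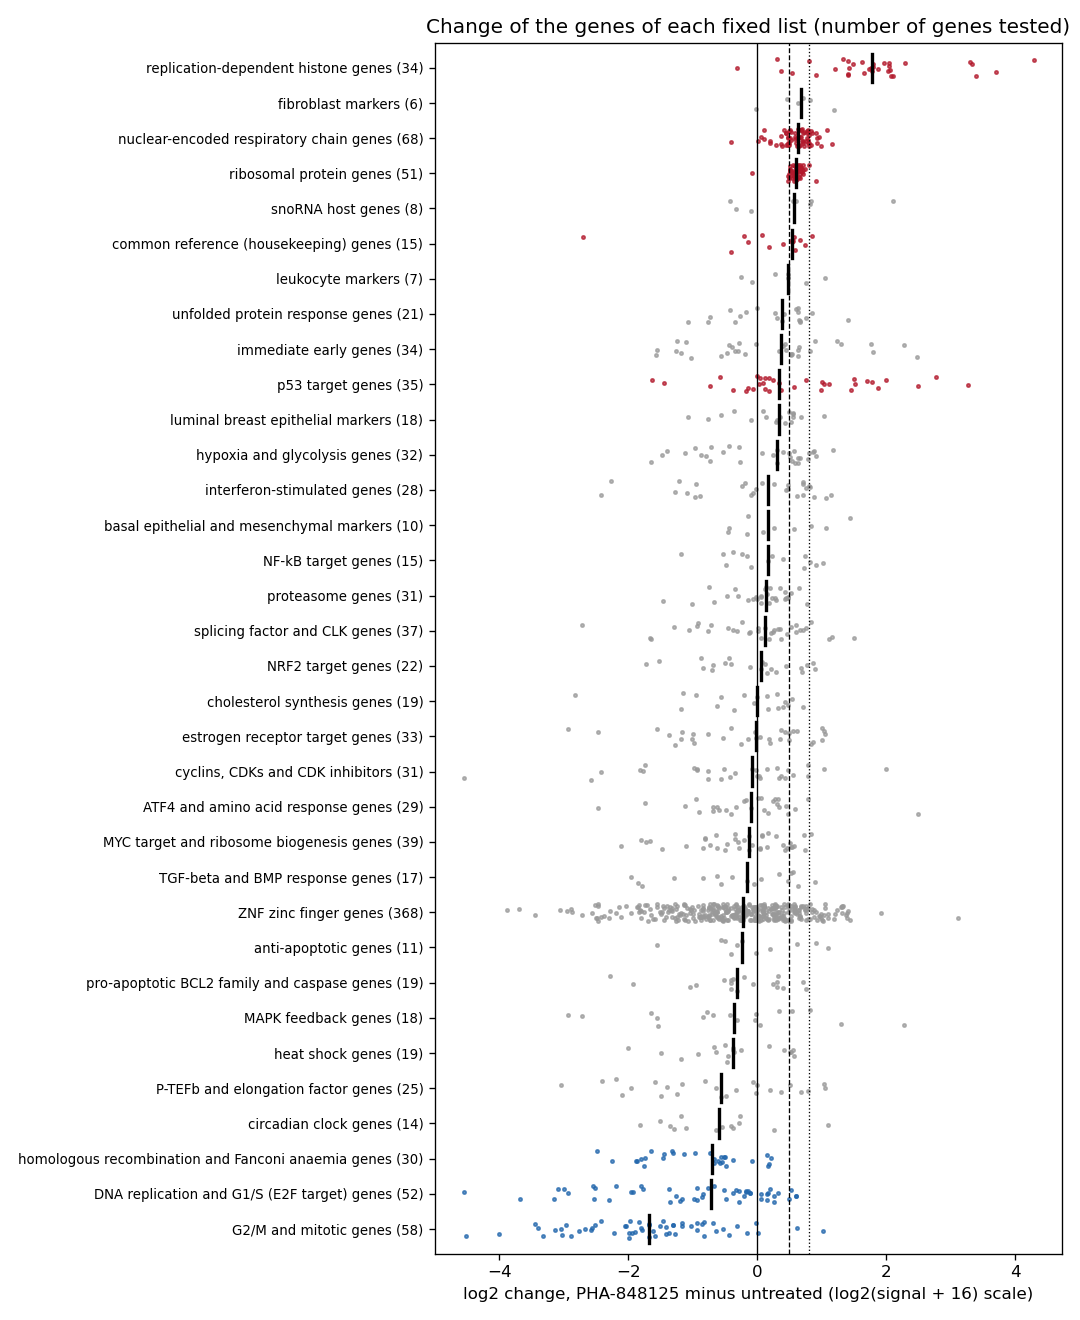
Log2 change (x axis, PHA-848125 minus untreated) of each tested gene of the 34 lists (rows, number of genes in parentheses), with a thick bar at the list's median. Lists shifted by camera with the preset correlation are red (higher) or blue (lower), and vertical lines mark 0 (solid) and the change of the hybridisation (dashed, 0.50) and poly-A spikes (dotted, 0.81), so that only the histone list has a median right of the dotted line.

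The largest rises were those of C1orf162 (6.56 ± 0.18), BCAR4 (5.14), BAAT (5.03), LINC00326 (4.93), PYCARD-AS1 (4.75), ALDH8A1 (4.65), MAP7D2 (4.61), DCAF4L1 (4.36), LOC389834 (4.29) and H4C4. In 8 of these 10 genes the untreated level lay below the level threshold, so that the size of the change depended on the pseudocount. With a pseudocount of 1, DCAF4L1 did not pass the level filter and was not tested. C1orf162 rose from a signal of 11.1 ± 2.77 to 2533 ± 87.2 (SD, n = 2), and BAAT, which conjugates bile acids to amino acids, from 5.86 ± 0.94 to 697 ± 15.9. The largest falls were those of C21orf91 (-4.77 ± 0.17), CCNE2, NDC80, SAP30 (-4.38), a subunit of the SIN3 histone deacetylase complex, KRCC1 (-4.14), AURKA, NABP1 (-3.95), ASF1A (-3.93), a histone chaperone, ZNF165 and ZBED5 (-3.80). The treated level lay below the threshold in 3 of them. All 20 genes kept their direction under every scaling tried.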

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

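All tests of explanations in this part were chosen after the results they concern had been seen, with the exception of the test of gene length without families of short genes.

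The spike-in controls, which the comparison of genes does not use, were brighter on the treated arrays, by 0.496 (log2) for the hybridisation spikes and 0.807 for the poly-A spikes. A single scaling factor per array would move both kinds alike, but the poly-A spikes gained 0.31 more, against a largest gap of 0.16 between replicate arrays. A larger share of signal in abundant transcripts is also argued against as the whole cause, since scaling to the mean of all probe sets left 0.26 of the hybridisation spikes' difference (largest replicate gap 0.12). Less polyadenylated RNA per amount of total RNA in treated cells stays open as an effect of the treatment: the median change of all genes was -0.76 against the poly-A spikes. It cannot be told apart from more of both kinds of spike-in added to both treated samples, which gives the same value. More of the poly-A spikes alone would not account for the median of -0.46 against the hybridisation spikes. Nor would less polyadenylated RNA alone, unless less labelled cRNA was also hybridised, and cRNA amounts were not examined here.

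The replication-dependent histone genes rose by a median of 1.77. Array scaling is argued against, since the median was still 1.00 against the poly-A spikes (lower quartile 0.61). Signal shared between near-identical copies is argued against as the whole cause, since members read by probe sets with the plain suffix had a median of 1.65 (lower quartile 1.36), 19 of 23 of them called higher. Polyadenylated histone transcripts taken up by oligo-dT priming stay open: the list's median exceeded that of 8 replacement histone genes by 1.28 (one-sided exact Wilcoxon rank-sum test, p = 2.8e-05; permutation test, run first, p = 0.0014), but this largely restates the rise. The replacement genes, whose transcripts carry tails, had a median of 0.49 with 6 called higher and 2 lower, a median that turned to -0.032 with quantile normalization and -0.0027 and -0.31 against the hybridisation and poly-A spikes, and no test here separates a tail from a higher transcript level under the treatment.

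Long genes fell against short genes: across 12257 genes, which are not independent replicates, Spearman's rho of gene length and log2 change was -0.190 (95% interval -0.207 to -0.173), and -0.150 to -0.193 over the scalings tried. Expression level is argued against, since the weakest rho in 5 equal bins of the untreated level was -0.132 (upper bound -0.093). A few families of short genes are argued against, since rho was -0.175 (upper bound -0.158) without the ribosomal protein, respiratory chain, histone and proteasome lists. RNA degradation in the treated samples stays open, since the 3' to 5' ratio of the controls disagreed. It changed by -0.041 (log2) for GAPDH and 0.074 for actin, and by 2.33 for 28S ribosomal RNA. The largest replicate gaps were 0.039, 0.092 and 0.658, so neither the GAPDH nor the actin ratio rose beyond its gap. The 28S ratio rests on a 3' probe set whose untreated signal, 20.8, lay below the level threshold, so it cannot decide. An effect of the treatment on long transcripts also stays open and was not tested.

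The control probe set for the 3' end of 28S ribosomal RNA, outside the genes compared, had a signal 6.80 times as high in the treated group, 141 ± 8.69 against 20.8 ± 1.04 (SD, n = 2), beside ratios of 1.95 for the middle and 1.33 for the 5' end. The untreated 3' signal lay below the level threshold, so the size of its ratio is uncertain. Among 4401 probe sets above the level threshold that have no single gene, 1366 were higher and 740 lower, with a median change of 0.23, against 0.02 for 22905 probe sets with a single gene.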

How the results depend on the processing

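Scaling to the poly-A spikes was chosen after seeing the data; the other alternatives were fixed before. The number of genes changed was 7646 and lay within 1.5 times of that in every alternative that tested genes. Testing all probe sets gave 15242 changed, 7618 for the number of genes higher, 7624 for the number of genes lower and 5597 for the number of genes changed at least 2-fold (here counts of probe sets), with 14 for the number of gene lists shifted, since more features were tested. The filter at the 75th percentile tested fewer genes and left 1486 changed at least 2-fold. Scaling to the hybridisation spikes gave 1085 higher and 6368 lower, and scaling to the poly-A spikes 271 higher, 7798 lower and 4970 at least 2-fold, by construction a shift of every gene. Of the 7646 calls, 4320 kept their direction and 665 were called the opposite way against the poly-A spikes. Camera with an estimated correlation called 0 lists and fry 30. Leaving out each array in turn gave 6561 to 7626 genes changed and 8 to 10 lists, with no named gene reversed; the lone array is then assumed to vary like the other group. Calls lost in at least 1 of these were those of BMP4, CDK9, DDIT3, EGFR, FCER1G, LCP1, OSGIN1 and RB1. With a pseudocount of 1 another probe set stood for PARP9 and was not called, and DCAF4L1 did not pass the level filter. Calls were lost by EGFR, FCER1G and OSGIN1 without a level filter, and by BMP4, CDK9, LCP1, OSGIN1 and RB1 without the variance trend. Besides the reversals given below, named genes lost their call in 18 cases against the poly-A spikes, 6 against the hybridisation spikes, 2 with median scaling, 2 with loess, 1 with quantile normalization, 3 with plain-suffix probe sets and 16 with the mean of all probe sets (ACTA2, BOK, CDK2, COL1A1, ERN1, ESR1, GUSB, KDM3A, PER3, PSMC2, RB1, RPL36, SEC24D, SKI, SKIL and XBP1). Named genes gained a call in 2 cases against the hybridisation spikes and 2 against the poly-A spikes. A named gene gained a call in 1 case each with quantile normalization, loess, plain-suffix probe sets and the mean of all probe sets. Without a level filter 11 lists were shifted, the 3 gained being the P-TEFb, circadian and luminal lists. With only plain-suffix probe sets the common reference call was lost and the proteasome list was called higher. Lists gained a call in an unchanged direction in 2 cases with quantile normalization and 6 over all probe sets. Against the hybridisation spikes there were 2 such cases and against the poly-A spikes 2. Not all of these lists are named here.

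No deviation shared by same-numbered arrays was seen: the correlation of same-numbered deviations across genes was 0.0038. This does not show whether the arrays were paired by design. With the replicate number as a block, the number of genes changed was 7780, and the luminal list was called higher.

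With quantile normalization the log2 change of CDK4 was -0.084, and the direction of the camera test turned, for lists called in either setting, in 2 (median log2 change relative to all genes, proteasome genes, -0.16; median log2 change relative to all genes, common reference (housekeeping) genes, -0.064, and -0.077 with cyclic loess). The sign of the median relative to all genes, though not such a call, also turned with quantile normalization for the splicing, ribosomal protein, cholesterol, hypoxia, NRF2 and luminal lists, and with loess for the ribosomal protein, proteasome, NRF2 and luminal lists. Against the hybridisation spikes the log2 change of CCND1 was -0.45, of CDK2 -0.16, of CDK4 -0.074 and of CDK9 -0.12. Against the poly-A spikes it was -0.76 for CCND1, -0.47 for CDK2, -0.38 for CDK4, -0.43 for CDK9, -0.081 for COL1A1, -0.062 for GUSB, -0.022 for LCP1, -0.042 for PSMB3, -0.072 for RPS12 and -0.0020 for RPS9. With the mean of all probe sets it was -0.94 for CCND1, -0.11 for CDK9, 0.40 for MDM2 and 0.34 for PER2. With only plain-suffix probe sets it was -1.91 for CCND1, 0.39 for IDI1, 0.71 for LUC7L3, 1.28 for MDM2 and 0.54 for PSMC2. The cause was not tested for the normalizations; for the last settings it is the other probe sets read. Genes near the pseudocount of 16 have the least certain size of change.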

Other observations

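The test of non-coding RNA genes was fixed before its result was seen. The exact test of the neighbours of histone genes replaced a permutation test after that test's result had been seen.

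Non-coding RNA genes moved apart from protein-coding genes. Of 609 tested, 138 rose (22.7%) and 80 fell (13.1%), with a median change of 0.22. Of 11443 protein-coding genes, 3373 rose (29.5%) and 3941 fell (34.4%), with a median of -0.01. Both shares were smaller among non-coding genes, more so that of falls. The largest rises included BCAR4, LINC00326 and PYCARD-AS1, which are non-coding. Their untreated levels lay below the level threshold, so they passed the filter only through the treated arrays. Compared with protein-coding genes of the same level, the median of non-coding RNA genes was higher by 0.22 (one-sided permutation test, p = 1e-05, the smallest the permutations can give). That level was the mean over all 4 arrays, the treated ones included. Genes are not independent replicates. The non-coding median turned to -0.22 and -0.51 against the hybridisation and poly-A spikes, where the protein-coding median was -0.48 and -0.78.

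Genes directly beside a replication-dependent histone gene were examined for a rise like that of the histone genes. Only 4 such genes were tested, RNF187 (0.87), HFE (0.73), H2AJ (0.41), itself a histone gene, and RRP1B (-0.65). Their median lay 0.56 above that of the other genes (one-sided exact Wilcoxon rank-sum test, p = 0.10), and the permutation test run first gave p = 0.061. Neither passed 0.05, and 4 genes are too few to decide.

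Gene length separated the changes in steps. Of 403 genes shorter than 2 kb, 48.9% rose and 8.68% fell, with a median change of 0.50. Of 1339 genes of 100 to 200 kb, 20.3% rose and 43.2% fell, with a median of -0.24, and of 796 longer genes the median was -0.14. The medians shift with the scaling, whereas the correlation of length and change was negative under every scaling tried.

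Several named genes had probe sets that moved in opposite directions. For PER2, 1 probe set changed by -1.51 and another, dimmer one by 2.19. For MYB, 1 changed by -2.93 and a dimmer one by 0.75. For ZFAS1, 1 changed by -1.77 while 3 brighter ones changed by 0.82 to 0.93. No explanation was tested for these differences.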
